A study of Arabidopsis thaliana with 17 samples.

How the data were processed

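Small RNAs were sequenced from wild-type Arabidopsis thaliana of the Col-0 accession. The libraries were made with version 1 of an Illumina small RNA cloning kit, per the labels' protocols. The deposited tables hold read counts: each line gives a sequence, the number of reads with that sequence, and 1 place where it matched the genome exactly. The build was TAIR10, per the submitters' processing notes. The aligner and the trimming were not given in the sources used here. The counts were used as deposited, with no molecular identifiers, so every interval and floor covers counting error only, since reads copied by PCR are not independent molecules.

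The series lists 17 samples. 3 of them, Floral A replicates 1 and 2, were not analysed here, which left 14 match tables. The 3 tables of Floral A replicate 3 are technical runs per the labels and were summed, giving 12 libraries that the labels' design calls biological replicates. Tables were compared over genes with at least 20 reads in a pair: the chi-square per degree of freedom was 1.16 between runs 2 and 3 of Floral A replicate 3, 9.81 and 9.48 between run 1 and each of these, and 8.23 to 60.9 between biological replicates of 1 group, so no pair of replicates was merged. Run 1 thus differed from its sister runs about as much as some biological replicates did, with 42.3% 24-nt reads against 53.9% and 57.6%, and was summed because the labels call it a technical run. Leaving it out gave 1935 called loci for floral tissue against leaf and 1052 against seedling, in place of 1947 and 1049. Coordinates were checked against the TAIR10.1 sequence and annotation, which share the nuclear and chloroplast coordinates of the build. The mitochondrial sequence differed, and no mitochondrial coordinate was used.

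Reads of 18 to 30 nt were counted once per sequence for library sizes and shares. Libraries held 143038 to 4384868 reads, and between 134797 and 4332212 of 18 to 30 nt. The pericentromere was taken as the 3 Mb on each side of a centromere placed at 15, 4, 14, 4 and 12 Mb on chromosomes 1 to 5. A 24-nt sequence with several matches was divided among them. Shares of 21-nt reads, of 24-nt reads and of pericentromeric 24-nt reads were compared with exact two-sided permutation tests of the difference in means, adjusted over the 12 tests by the Benjamini-Hochberg method. The smallest p these tests can give is 0.0179 for 5 against 3 libraries and 0.100 for 3 against 3 or 2 against 3. The permutations crossed labs, so they do not separate tissue from lab, and all seedling libraries came from lab A. Shares of single libraries carry 95% Wilson intervals.

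Mature small RNAs were counted as reads identical to 112 sequences listed from memory of published annotation. Of these, 70 passed edgeR's expression filter. Sequences with several genomic copies were counted once, so copies cannot be told apart. Their library size was the number of 18 to 30 nt reads, with no further scaling, and levels are given as RPM, reads scaled to this library size. Loci were annotated genes, counted by uniquely matching reads of 20 to 25 nt whose midpoint lay in the gene, on both strands. Structural RNA genes and organelles were left out, 4826 genes passed the filter, and levels are given as TMM-scaled CPM. Overlapping genes share reads under this rule, and members of near-identical families are uncertain because shared reads were dropped. Leaf A replicate 2 lists no organelle match, so there a read that also matches an organelle counted as nuclear.

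Both tables were tested with edgeR 4.0.16 (quasi-likelihood F-test, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, in 1 additive model of tissue and lab over the 12 libraries. The comparison of Floral A with Floral B is the lab term of that model, estimated from floral and leaf libraries together. The fitted changes adjust for lab, so they differ from ratios of the plain means. The single silique and Leaf B libraries were assumed to vary like the others. Fitted log2 changes are given with their standard error and means with their SD. A fold against a group with 0 reads was computed against a floor of 3 reads over the group's summed libraries, and a ratio to a group with 1 to 3 reads divides the mean of the other group by those reads over the summed library sizes, with a 95% interval. These ratios differ from the ratio of the printed means. The floors and these intervals carry the counting error of the lower group alone.

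Lists were fixed before the data were examined, as were the tests, the groups and most other settings. The mature lists were the miR172 family (adult phase and floral identity), vegetative phase miRNAs, auxin pathway miRNAs, Brassicaceae-restricted miRNAs, developmental miRNAs that target transcription factors, nutrient and metal miRNAs, pollen-associated miRNAs, silencing pathway miRNAs, triggers of trans-acting siRNAs, and trans-acting siRNAs. The locus lists were trans-acting siRNA loci, NLR disease resistance genes and PPR genes that yield secondary siRNAs, auxin receptor and other miRNA-targeted genes that yield siRNAs, genes with siRNA-targeted promoters or repeats, hairpin siRNA loci and genes noted as transposable elements. The annotation marks only 24 genes with a transposable element note. Annotated pseudogenes, protein-coding genes, long non-coding RNA genes and miRNA genes were added as lists after the data were seen. Lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation.

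Named items followed a fixed rule. In each comparison these were the 10 called mature small RNAs with the largest change each way and a mean of at least 10 RPM in a group. Called loci were the 5 largest each way with a mean of at least 10 CPM and no overlap between the libraries of the groups. The following were always named: miR156a, miR157a, miR159a, miR165a, miR166a, miR168a, miR172a, miR390a, miR845a, miR845b, and the trans-acting siRNA sequences and loci. List members were named as examples by the size of their change. The value of 1 member of the NLR list is not reported here. The sequences of miR845b and tasiR-ARF-D8 had too few reads to be tested, and siR1511 had 0 reads in every library.

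Counts were simulated with the real overall means and library sizes but without the real differences between tissues and labs, so the rates do not cover those. EdgeR recovered 10.0% of 4-fold and 20.0% of 16-fold changes among 70 mature small RNAs for floral tissue against leaf, with 0 false calls among 3. It recovered 0% and 60.0% for floral tissue against seedling, with 1 false call among 7. Among 4826 loci it recovered 21.0% and 71.0% for floral tissue against leaf, with 4 false calls among 96, and 16.0% and 70.0% for floral tissue against seedling, with 6 false calls among 92. It made 0 calls for leaf against seedling and for the labs, where no change was simulated.

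Other settings chosen at that time were TMM scaling or all-read scaling, DESeq2 1.42.0, no filter on low counts, length variants of 19 to 24 nt that share the first 18 bases, 24-nt reads only, all matches divided by their number, 1000-bp bins, uniquely matching reads, distinct sequences, reads without structural RNA or organelle matches, a pericentromere of 2 Mb, 1 mean per group, lab A alone, and leaving out each library. A library size without structural RNA, organelle and run-of-A reads (12 or more A) and the omission of the first run of Floral A replicate 3 were added after the data were seen. Other steps used limma 3.58.1, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.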

Results

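Small RNAs were measured by sequencing in floral tissue, leaves, seedlings and siliques, the fruits of Arabidopsis. Floral and leaf libraries came from both of the labs in the labels, called lab A and lab B here. The seedling libraries came from lab A and the silique library from lab B. There were 2 Floral A libraries (replicates 3 and 4), 3 Floral B, 2 Leaf A, 1 Leaf B, 3 Seedling A and 1 Silique B library. Depth was 2802565 and 341880 reads in Floral A, and 955994, 408039 and 349920 in Floral B. The leaf libraries held 1342573 reads (Leaf B), 4363918 and 202218 (Leaf A). The seedling libraries held 4384868, 2315328 and 2167987 reads, and the silique library held 143038. The design asks how the small RNA population differs between tissues, and how far floral samples of the 2 labs differ.

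The 24-nt share of reads differed between the libraries of the tissues. The 24-nt class, which holds the siRNAs that guide DNA methylation, made up 53.6% ± 11.9 of reads in floral tissue (n = 5), against 15.1% ± 2.54 in leaf (n = 3) and 21.7% ± 7.69 in seedling (n = 3). In the silique library it made up 54.2% (95% interval 54.0 to 54.5). Every floral library lay above every leaf and seedling library, giving differences of 38.5 and 31.9 percentage points, each with an exact permutation p of 0.0179, the smallest possible, and an adjusted p of 0.0714. Within lab A these differences were 29.4 and 22.6 points, and within lab B floral tissue exceeded leaf by 44.4 points. Counting distinct sequences in place of reads gave 29.0 points against leaf and 11.9 against seedling. Reads of 18 nt made up 11.5% in Leaf B and 11.0% and 8.97% in Leaf A. They made up 0.260% to 1.27% in floral libraries and 2.46% to 4.74% in seedling. Fragments of longer RNAs may thus take part of the leaf reads and lower their 24-nt share, which was not tested. Leaf and seedling differed by less than their spread in this class (-6.58 points, exact permutation p = 0.300, adjusted p = 0.450). The 21-nt class, which holds most miRNAs, made up 15.8% ± 9.55 in floral tissue, 19.4% ± 2.83 in leaf and 21.0% ± 3.72 in seedling, with exact permutation p of 0.571, 0.393 and 0.600 for the 3 pairs. The floral minus leaf difference was 3.89 points in lab A and -6.78 in lab B.

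The seedling libraries stood apart in 20-nt reads, at 43.2%, 23.3% and 24.6% of reads. A single sequence, miR156a of 20 nt, made up 18.2% to 37.8% of their reads. The 112 listed mature sequences together took 40.1% ± 9.50 of seedling reads, 9.45% ± 9.14 of floral reads, 6.44% ± 2.05 of leaf reads and 0.461% of silique reads (95% interval 0.427 to 0.499). Pericentromeric DNA matched 56.2% ± 1.75 of 24-nt reads in seedling, 47.9% ± 2.00 in floral tissue and 45.2% ± 5.38 in leaf, and 37.8% in the silique library. The difference of -8.28 points between floral tissue and seedling had an exact permutation p of 0.0179 and an adjusted p of 0.0714, and was -9.82 points within lab A. For leaf against seedling it was -11.0 points (exact permutation p = 0.100, the smallest possible, adjusted p = 0.200), and for floral tissue against leaf 2.71 points (exact permutation p = 0.339), with 4.24 in lab A and -2.40 in lab B. Structural RNA took 22.1% ± 4.46 of reads in Leaf A, 0.981% ± 0.141 in Floral A and 14.9% in the silique library. Organelle matches took 38.0% in Leaf A replicate 1, 0% in Leaf A replicate 2 and 16.5% in Leaf B replicate 1.

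**Figure D1:**
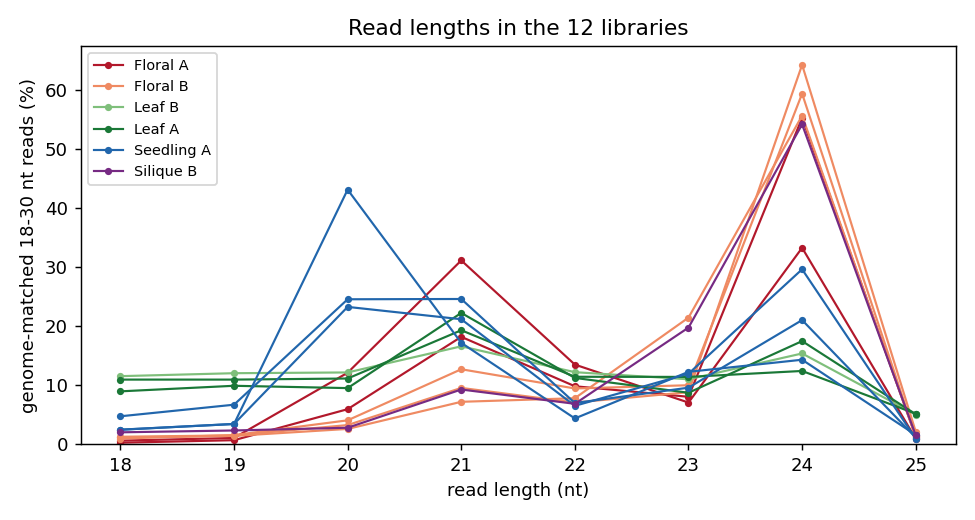
Share of genome-matched reads (percent, vertical axis) by read length (nt, horizontal axis) in each of the 12 libraries. The 24-nt class leads in floral tissue and the silique library, and the 20-nt class is high in the seedling libraries, at 43.2%, 23.3% and 24.6%.

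The comparison of floral tissue with leaf asks which small RNAs belong to flowers. The miRNAs miR172c and miR172a, which repress APETALA2-like genes, were far higher in floral tissue: miR172c stood at 1239 ± 1558 RPM in 5 floral libraries and had 0 reads in 3 leaf libraries, at least 2061-fold higher, and miR172a stood at 6584 ± 7915 against 131 ± 99.0 RPM. Floral tissue was also higher in miR156h (2552 ± 3616 against 3.57 ± 5.95 RPM), miR827 (89.0 ± 112 against 0.181 ± 0.314 RPM) and several miRNAs restricted to the Brassicaceae, such as miR867. It was lower in miR163 (666 ± 1034 against 4624 ± 2427 RPM) and had 0 reads of miR850, at least 21.8-fold lower than leaf. For miR163 the Floral A libraries had 6.10 and 17.7 RPM and Floral B had 2457, 208 and 639. Leaf had 5101, 1995 and 6777 RPM, so Floral B replicate 1 lay above Leaf A replicate 1. In all, 15 mature small RNAs were higher and 4 lower among 70 tested, against 12 and 9 with TMM scaling and 11 and 13 with DESeq2. TMM scaling moved the median change of all tested mature small RNAs from 0.77 to -0.55 here, from 1.54 to -0.81 against seedling, from 0.48 to -0.53 between leaf and seedling, from 1.36 to -0.32 between the labs and from -4.67 to -3.53 for silique.

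By the edgeR test, miR172c (chromosome 3, 20587991 to 20588011 and 3599791 to 3599811, TAIR10) had a log2 change of 12.67 ± 2.58 (adjusted p = 8.74e-05), miR172e 6.01 ± 1.87 (0.00997) and miR172a 5.75 ± 1.71 (0.00904). These are all 3 members of the family list (camera adjusted p = 0.0434, or 0.982 with an estimated correlation), 3 of 3 also when adjusted over the list alone, with TMM scaling and with DESeq2. Among 27 tested Brassicaceae-restricted miRNAs, 5 were higher, 2 lower and 20 not called (camera adjusted p = 0.978, or 0.982 with an estimated correlation), likewise 5 and 2 when adjusted over the list alone, and 3 and 3 with DESeq2. Its higher members were miR867 (chromosome 4, 11375387 to 11375407; at least 76.0-fold, adjusted p = 0.00654), miR771 (at least 50.1-fold, 0.00890), miR780 (at least 33.8-fold, 0.0141), miR839 (207-fold, 95% interval 57.4 to 1711, 0.00904) and miR856 (at least 22.6-fold, 0.0243). Here and below, ratios with an interval divide the mean of the higher group by the summed reads of the lower group over its summed library sizes, so they differ from the ratio of the means. Its lower members were miR850 (chromosome 4, 7845756 to 7845777; adjusted p = 0.00890) and miR163 (chromosome 1, 24884359 to 24884382; -6.97 ± 2.20, 0.0103). Developmental miRNAs had 8 of 29 members higher, 2 lower and 19 not called (8 and 3 adjusted over the list alone; camera adjusted p = 0.978, or 0.982 with an estimated correlation). With TMM scaling this split was 6 and 6, and with DESeq2 7 and 8. They included miR394a at 6.08 ± 1.89, miR171a at 4.83 ± 1.81, miR170 at 5.44 ± 1.96, miR169d at 7.49 ± 2.45, and miR169a at -4.66. Of these, miR169d was high in Floral A alone (199 and 216 RPM), with 1.10, 0 and 0 RPM in Floral B against 0, 1.09 and 0 in leaf. Another member, miR167d (chromosome 1, 11137556 to 11137577), which targets auxin response factors, fell by 5.76 (adjusted p = 0.0203) and was the called member among 5 auxin pathway miRNAs (median 1.18, mean 0.04; camera adjusted p = 0.978, or 0.982 with an estimated correlation; 1 lower adjusted over the list alone). Counting its length variants turned it to 1.49 (adjusted p = 0.482). That setting takes any read with the same first 18 bases, so it may include other miR167 members.

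Of the nutrient miRNAs, 1 of 5 was higher in floral tissue, the phosphate-responsive miR827 (chromosome 3, 22122811 to 22122831; 8.37 ± 2.29, adjusted p = 0.00654; 222-fold, 95% interval 61.5 to 1833). That list had a median of -0.20 and a mean of 0.63, with 1 higher adjusted over the list alone (camera adjusted p = 0.978, or 0.982 with an estimated correlation). The pollen-associated miR845a had 39.4 ± 54.5 RPM in floral tissue and 0 in leaf (at least 65.5-fold, adjusted p = 0.0382), and its call was lost with TMM scaling, DESeq2, no filter or the library size without structural RNA, and without any of 10 of the 12 libraries. Of 4 vegetative phase miRNAs only miR156h was called, at 6.16 ± 1.91 (camera adjusted p = 0.761, or 0.982 with an estimated correlation), and miR156a had 1.18 ± 1.80 (adjusted p = 0.679) and miR157a -0.18 ± 1.47. In lab A alone edgeR gave 5.82 for miR156a and 2.33 for miR157a (both called), and in an edgeR interaction that rests on the single Leaf B library the changes of miR156a and miR156h were 7.53 and 11.22 larger in lab A (adjusted p = 0.0234 and 0.00687). Trans-acting siRNA triggers and the 2 tested trans-acting siRNAs had 0 edgeR calls, with miR390a at 1.18 ± 1.35, tasiR-ARF-D7 at 2.67 ± 1.53 and siR255 at -1.72 ± 2.12. DESeq2 called 1 trigger higher and 1 trans-acting siRNA lower (camera adjusted p = 0.745 and 0.978, or 0.982 with an estimated correlation). The silencing pathway miRNAs, which target DCL1, AGO1 and AGO2, had 0 of 3 called by edgeR or DESeq2 in any of the 5 comparisons, also adjusted over the list alone (camera adjusted p from 0.745 to 0.978, or 0.982 with an estimated correlation), with miR168a at 1.17 ± 1.45 here. The leaf polarity miRNAs miR165a and miR166a had -0.16 ± 1.34 and 0.05 ± 1.33, and miR159a, which targets GAMYB-like genes, had -5.44 ± 2.26 (adjusted p = 0.0567). The directions of miR166a and miR168a flipped with TMM scaling. The count of 19 became 3 without Leaf A replicate 1 and 10 without Floral A replicate 4. Of the 15 named calls, miR172c alone held in every alternative and with every library left out.

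**Figure D2:**
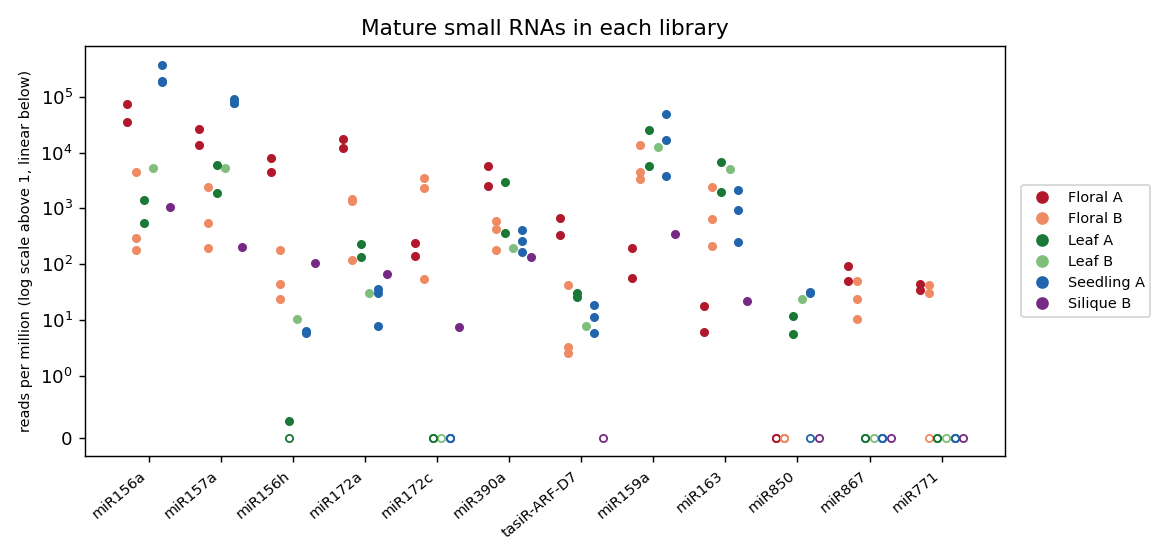
Level of 12 mature small RNAs (RPM, log scale above 1 and linear below, vertical axis) in each library, coloured by tissue and lab, with open circles for 0 reads. All 5 floral libraries hold miR172c and all leaf and seedling libraries have 0, and miR156a is highest in the 3 seedling libraries.

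Small RNAs from annotated genes also differed between floral tissue and leaf. The MIR780 locus gave 7893 ± 11060 CPM in floral tissue and 0 reads in leaf, and the trans-acting siRNA locus TAS3b gave 1242 ± 877 against 21.2 ± 6.70 CPM. Leaf gave more at LHCB2.2, a light-harvesting gene (450 ± 634 against 0 CPM), and at CRD1, a chlorophyll synthesis gene (946 ± 1489 against 0.310 ± 0.694 CPM). In all, 744 loci were higher and 1203 lower in floral tissue among 4826 tested. With the total library size 2175 were higher and 595 lower, and the median change of all tested loci moved from 0.01 to 1.95 (-0.48 to 0.14 against seedling, -0.20 to -1.63 between leaf and seedling, 0.13 to -0.34 between the labs and -0.85 to -1.43 for silique).

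The higher loci gave mainly 24-nt reads from both strands, with medians of 71.9% 24-nt and 53.1% on the strand of the gene. The 1050 lower protein-coding loci gave leaf reads with medians of 13.3% 24-nt and 100% on the strand of the gene. By edgeR, MIR780 (AT4G14811, chromosome 4, 8504141 to 8504314, TAIR10) and the overlapping AT4G14810 shared the same 10424 floral reads (14.35 ± 1.98, adjusted p = 1.01e-05, at least 834-fold), of which the listed mature miR780 made up 77. Next came AT1G08077, a long non-coding RNA gene (chromosome 1, 20926165 to 20926446; at least 154-fold), AT1G20290 (at least 114-fold) and the pseudogene AT5G36297 (at least 92.2-fold). The largest decreases were at AT1G07940, an elongation factor gene (chromosome 1, 2462949 to 2465545; at least 271-fold lower), AT1G07280 (at least 177-fold), LHCB2.2 (AT2G05070, chromosome 2, 1799234 to 1800472; at least 175-fold), COL4 (AT5G24930, chromosome 5, 8589457 to 8590949; at least 131-fold) and CRD1 (AT3G56940; 1103-fold, 95% interval 198 to 43578). DESeq2 did not call AT1G07940, a member of a near-identical family, and the other named loci were called in every alternative that could test them and with every library left out.

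Among the 8 trans-acting siRNA loci, 2 were higher, 1 lower and 5 not called in floral tissue against leaf, likewise adjusted over the list alone (median -0.44, mean 0.12; camera adjusted p = 0.784, or 0.925 with an estimated correlation). TAS3b (AT5G49615, chromosome 5, 20134200 to 20134786) was higher by 6.09 ± 0.95 (adjusted p = 2.59e-05) and TASIR-ARF (AT5G57735, chromosome 5, 23394005 to 23394500) by 4.31 ± 0.92 (0.000635). The locus AT3G25795 (chromosome 3, 9417551 to 9418705) was lower by edgeR at -6.99 ± 1.11 (2.94e-05; 146-fold, 95% interval 40.3 to 1203). TAS1A, TAS1B, TAS1C and TAS2 had changes of -0.43 ± 1.02, -1.22 ± 0.93, -0.45 ± 1.07 and -0.83 ± 0.98, all of which turned positive with the total library size, and TAS3 had 0.44 ± 0.99. Of 6 tested NLR genes, 5 were lower in floral tissue, again 5 adjusted over the list alone and 3 with the total library size (camera adjusted p = 0.00581, or 0.352 with an estimated correlation). They included AT5G38850 (-6.83), AT1G15890 (-5.39), AT5G43740 (-3.20) and RPP4 (-2.81), while AT1G12290 had -0.76. Of 5 miRNA-targeted siRNA sources, AGO1 (-5.42), TIR1 (-2.77) and AFB2 (-2.54) were lower, 3 also adjusted over the list alone (camera adjusted p = 0.313, or 0.683 with an estimated correlation), and with the total library size 1 was higher and 1 lower. The AGO1 call rested largely on Leaf B replicate 1, which held 1729 of the 1838 leaf reads. Of 12 PPR genes, AT1G63130 was lower at -1.85, with 0 adjusted over the list alone (median -0.06, mean 0.01; camera adjusted p = 0.972, or 0.990 with an estimated correlation), and with the total library size 3 were higher. Of 11 tested genes with a transposable element note, 1 was higher and 1 lower, and 1 and 0 adjusted over the list alone (camera adjusted p = 0.864, or 0.925 with an estimated correlation). Of 2 tested genes with siRNA-targeted promoters or repeats, 0 were called by edgeR, also adjusted over the list alone, or by DESeq2 (camera adjusted p = 0.913, or 0.952 with an estimated correlation). Hairpin siRNA loci had too few reads to be tested in any comparison. The count of 1947 called loci became 1145 without Floral A replicate 3 and 1260 without Leaf A replicate 1.

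The comparison of floral tissue with seedling repeats this question against young plants. Again miR172c and miR172a were far higher in floral tissue, with miR172c at least 3555-fold higher and miR172a at 6584 ± 7915 against 24.7 ± 14.8 RPM (5 and 3 libraries). Also higher by the fit were miR156h (2552 ± 3616 against 6.14 ± 0.335 RPM), miR173, the trigger of TAS1 and TAS2 siRNAs (10707 ± 15549 against 444 ± 209 RPM), and the trans-acting siRNA tasiR-ARF-D7 (214 ± 299 against 11.9 ± 6.27 RPM). The last 2 were high in Floral A alone: the Floral B libraries had 403, 107 and 434 RPM of miR173 and 3.29, 2.60 and 42.2 RPM of tasiR-ARF-D7, against 226 to 643 and 5.77 to 18.3 RPM in seedling. Seedlings were higher in miR159a (23315 ± 23670 against 4374 ± 5588 RPM) and miR169a (88.9 ± 32.8 against 3.03 ± 5.28 RPM). For miR159a the Floral A libraries had 56.7 and 198 RPM. The Floral B libraries had 4440, 3425 and 13749 RPM, which overlapped the seedling values of 3774, 16537 and 49635. The vegetative phase miRNA miR156a stood at 249750 ± 111150 RPM in seedling and 22925 ± 32323 in floral tissue with no overlap between libraries, but its change of -3.13 ± 1.44 did not pass (edgeR adjusted p = 0.0827). In Floral A replicate 4 the most frequent sequence, 9.98% of reads, was miR156a with 1 more T at its start. Neither the exact count nor the count of length variants includes that sequence, so the miR156a levels given leave it out. In all, 16 mature small RNAs were higher and 3 lower in floral tissue, against 12 and 14 with TMM scaling and 14 and 12 with DESeq2.

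By edgeR, miR172c changed by 11.33 ± 2.29 (adjusted p = 7.11e-05), miR172a by 8.97 ± 2.02 (0.000248) and miR172e by 7.46 ± 2.00 (0.00209), so 3 of 3 in the family list were higher, also adjusted over the list alone (camera adjusted p = 0.0434, or 0.982 with an estimated correlation). Of 29 developmental miRNAs, 7 were higher, 2 lower and 20 not called, likewise over the list alone, 6 and 8 with TMM scaling and 7 and 9 with DESeq2 (camera adjusted p = 0.745, or 0.982 with an estimated correlation). They included miR171a (5.37 ± 1.85), miR394a (6.35 ± 1.90), miR169d (6.77 ± 1.96), miR159a (chromosome 1, 27713234 to 27713254; -6.59 ± 2.48, adjusted p = 0.0335) and miR169a (-4.02 ± 1.59, 0.0439). The rise of miR169d was in Floral A alone (199 and 216 RPM). Floral B had 1.10, 0 and 0 RPM, against 0.231, 3.55 and 1.48 in seedling. Of 27 Brassicaceae-restricted miRNAs, 7 were higher and 1 lower (9 and 1 adjusted over the list alone, 6 and 5 with TMM scaling, 5 and 2 with DESeq2; camera adjusted p = 0.978, or 0.982 with an estimated correlation). The higher ones were miR867 (at least 131-fold), miR771 (at least 86.4-fold), miR780 (at least 58.2-fold), miR856 (at least 39.0-fold), miR839 (715-fold, 95% interval 128 to 28237), miR851 (7.07 ± 2.27) and miR173 (5.02 ± 1.67, adjusted p = 0.0148). The lower one was miR850 (at least 32.7-fold, adjusted p = 0.00392). In the vegetative phase list miR156h (chromosome 5, 22597087 to 22597106; 9.02 ± 1.99, 0.000248) was the 1 called member of 4, and miR157a had -2.82 ± 1.43 (list median -2.74, mean 0.10; camera adjusted p = 0.548, or 0.982 with an estimated correlation). With TMM scaling or DESeq2 the other 3 members were called lower. Of the 2 triggers miR173 was called (2 adjusted over the list alone; camera adjusted p = 0.712, or 0.982 with an estimated correlation), and miR390a had 3.84 ± 1.61 (0.0553). Of the 2 trans-acting siRNAs tasiR-ARF-D7 was higher by 4.87 ± 1.69 (0.0181; camera adjusted p = 0.978, or 0.982 with an estimated correlation), and siR255 had -1.19 ± 2.09. Among nutrient miRNAs miR827 was the 1 called of 5 at 4.52 ± 1.77 (0 over the list alone, 0 higher and 1 lower with DESeq2; camera adjusted p = 0.978, or 0.982 with an estimated correlation). Of the auxin pathway miRNAs 0 of 5 were called by edgeR, while DESeq2 called 1 higher and 1 lower (camera adjusted p = 0.978, or 0.982 with an estimated correlation). Not called were miR165a (-0.49 ± 1.51), miR166a (1.03 ± 1.51, which flipped with TMM scaling), miR168a (2.42 ± 1.45) and miR845a (3.49 ± 2.19). The count of 19 became 9 without any of the 3 seedling libraries and 12 without Floral A replicate 4, and the miR159a call was lost without any of 6 libraries (Floral A replicates 3 and 4, Floral B replicate 1 and each seedling library). The tasiR-ARF-D7 call was lost with TMM scaling and without Floral A replicate 4 or any seedling library, and the miR169a call in 4 other settings and without any of 9 libraries.

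At annotated genes, 525 loci were higher and 524 lower in floral tissue than in seedling. The long non-coding RNA genes AT1G06417 and AT2G05925 gave 2639 ± 865 and 3879 ± 806 CPM in floral tissue and 0 reads in seedling, and AT3G23650 gave 4942 ± 3449 against 0.679 ± 1.18 CPM. Decreases were called at the pseudogene AT5G31804 (0 against 54.9 ± 25.1 CPM), at NAI2, an endoplasmic reticulum body gene, and at PKS1, a phytochrome kinase substrate gene (0 against 105 ± 57.7 CPM). With the total library size 661 were higher and 310 lower, and with DESeq2 591 and 367.

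By edgeR, MIR780 and AT4G14810 (13.22 ± 1.55, adjusted p = 1.65e-06; 5368-fold, 95% interval 1486 to 44325) led the floral loci. They were followed by AT1G06417 (chromosome 1, 11139772 to 11140052; at least 1197-fold), AT2G05925 (chromosome 2, 5661128 to 5661510; at least 1759-fold) and AT3G23650 (chromosome 3, 8510689 to 8511196; 6722-fold, 95% interval 1206 to 265510). Floral reads at these last 3 loci were 73.7%, 69.9% and 81.0% 24-nt. The 265 lower protein-coding loci gave seedling reads with medians of 94.1% on the strand of the gene and 15.4% 24-nt. Lower loci were AT5G31804 (chromosome 5, 11715184 to 11721564; at least 21.3-fold), NAI2 (AT3G15950; at least 13.3-fold), AT1G36925 (-8.35 ± 1.09, adjusted p = 4.00e-06), PKS1 (AT2G02950, chromosome 2, 854077 to 856725; at least 40.7-fold) and the jacalin-type gene JAL22 (AT2G39310; 41.9-fold, 95% interval 7.52 to 1655). Of the 8 trans-acting siRNA loci, TAS3b was higher (4.18 ± 0.83, adjusted p = 0.000451) and AT3G25795 lower (-6.11 ± 1.34, 0.00147), 1 each also adjusted over the list alone, and 3 and 1 with DESeq2 (camera adjusted p = 0.278, or 0.683 with an estimated correlation). The others had 0.77 ± 1.08 (TAS1A), -0.09 (TAS1B, which flipped with either other scaling), 0.64 (TAS1C), 0.64 ± 1.11 (TAS2), 1.74 ± 1.07 (TAS3) and 1.55 ± 0.67 (TASIR-ARF). Of the NLR genes 1 of 6 was lower (AT5G38850, -4.61; camera adjusted p = 0.576, or 0.770 with an estimated correlation). Of the miRNA-targeted siRNA sources 1 of 5 was higher (AFB3, 2.80; median -0.02, mean 0.58; camera adjusted p = 0.557, or 0.770 with an estimated correlation). Of the PPR genes 1 of 12 was higher (AT5G41170, 7.68; camera adjusted p = 0.381, or 0.770 with an estimated correlation). Each of these counts was the same adjusted over the list alone. Of 11 genes with a transposable element note 1 was lower (camera adjusted p = 0.756, or 0.813 with an estimated correlation), and of 2 genes with siRNA-targeted promoters or repeats 0 were called by edgeR or DESeq2 (camera adjusted p = 0.480, or 0.683 with an estimated correlation). The named loci were called in every alternative that could test them and with every library left out, and the count of 1049 became 548 without Floral A replicate 3.

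**Figure D3:**
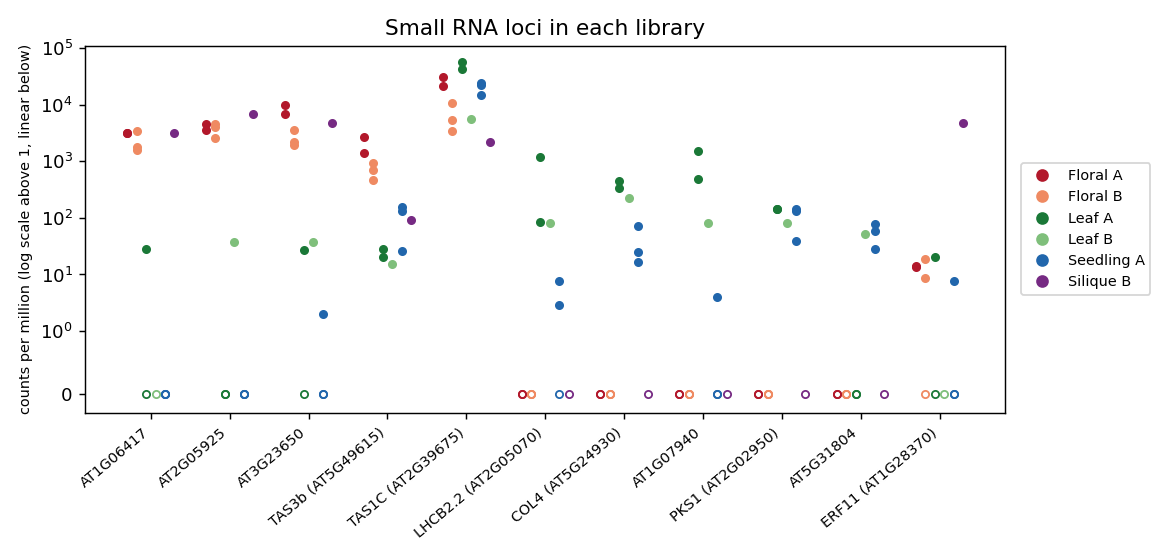
Level of 11 small RNA loci (CPM, log scale above 1 and linear below, vertical axis) in each library, coloured by tissue and lab, with open circles for 0 reads. AT1G06417 and AT2G05925 have reads in all 5 floral libraries and 0 in the 3 seedling libraries, and ERF11 is highest in the silique library.

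Leaf against seedling compares the vegetative samples, leaves and seedlings. The plain means of 2 vegetative phase miRNAs were lower in leaf, with miR156a at 2447 ± 2588 against 249750 ± 111150 RPM and miR157a at 4444 ± 2225 against 82729 ± 8017 RPM in 3 libraries each, without overlap. Neither passed edgeR's test (-4.31 ± 2.24, adjusted p = 0.543, and -2.64 ± 1.93, adjusted p = 0.692), but in lab A alone both were called, each with a larger decrease. At annotated genes 777 loci were higher and 270 lower in leaf. Small RNAs were higher in leaf at ROC2, a cyclophilin gene (348 ± 565 CPM against 0), and UBQ14, a polyubiquitin gene (595 ± 456 against 1.27 ± 2.21 CPM), and lower at pseudogenes such as AT2G10253 (0 against 72.3 ± 26.1 CPM).

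EdgeR called 0 of 70 mature small RNAs here, with 3 at an unadjusted p under 0.05, and DESeq2 called 5. The 4 vegetative phase miRNAs had a median of -2.97, with miR156h at 2.86 ± 2.35, and 0 called (camera adjusted p = 0.00307, or 0.982 with an estimated correlation), 3 of which DESeq2 called lower. Every other mature list had 0 edgeR calls, also adjusted over the list alone, with camera adjusted p of 0.534 or more (0.982 with an estimated correlation), and DESeq2 called 1 miRNA of the miR172 family and 1 Brassicaceae-restricted miRNA higher. Values were miR172a 3.22 ± 1.62, miR390a 2.67 ± 1.55, tasiR-ARF-D7 2.20 ± 1.71, miR168a 1.25 ± 1.77, miR166a 0.99 ± 1.52, siR255 0.53 ± 1.43, miR165a -0.33 ± 1.46 and miR159a -1.14 ± 1.46. Those of miR166a and siR255 flipped with TMM scaling, miR159a with DESeq2 and miR165a with the library size without structural RNA. Without Leaf B replicate 1 the count was 1.

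At loci, the largest increases in leaf were ROC2 (AT3G56070, chromosome 3, 20806566 to 20808168; at least 158-fold, adjusted p = 5.59e-05), AT1G07940 (475-fold, 95% interval 132 to 3923, lost with DESeq2), UBQ14 (AT4G02890; 405-fold, 95% interval 112 to 3344), AT1G07017 (318-fold, 95% interval 88.0 to 2626) and KCS1, a wax synthesis gene (AT1G01120; at least 39.5-fold). The 777 higher loci gave leaf reads with medians of 100% on the strand of the gene and 13.9% 24-nt, and the leaf reads of ROC2, UBQ14 and KCS1 all lay on that strand. The largest decreases were AT1G12615 (at least 2.50-fold lower), AT4G04078 (at least 3.05-fold), AT3G42810 (chromosome 3, 14919657 to 14920215; at least 6.51-fold), AT2G10253 (chromosome 2, 3927980 to 3928813; at least 7.64-fold) and EXT11 (at least 3.18-fold). AT1G12615, AT4G04078 and EXT11 were lost with 1 mean per group and without Leaf B or Leaf A replicate 1. Of 6 NLR genes 3 were higher in leaf, and 5 adjusted over the list alone (camera adjusted p = 0.00321, or 0.352 with an estimated correlation), and 2 with the total library size. Of 5 miRNA-targeted siRNA sources AGO1 (4.40) and TIR1 (2.76) were higher, and 4 adjusted over the list alone (camera adjusted p = 0.0170, or 0.385 with an estimated correlation), but Leaf B replicate 1 held 1729 of the 1838 leaf reads of AGO1. Of 8 trans-acting siRNA loci TASIR-ARF was lower (-2.76 ± 0.98, adjusted p = 0.0450), with 0 adjusted over the list alone (median 1.11; camera adjusted p = 0.754, or 0.925 with an estimated correlation), and its call was lost with 3 alternatives and without any of 9 libraries. TAS1A had 1.199 ± 0.946, TAS1B 1.13 ± 0.87, TAS1C 1.09 ± 1.13, TAS2 1.47 ± 1.09, TAS3 1.31 ± 0.96, TAS3b -1.91 ± 0.96 and AT3G25795 0.88 ± 1.04, the last of which flipped with the total library size. Of 2 genes with siRNA-targeted promoters or repeats DML1, a DNA demethylase gene, was higher (3.83; camera adjusted p = 0.754, or 0.813 with an estimated correlation). DML1 had 14 leaf reads, 0% of them 21-nt and 0% 24-nt, and 4 seedling reads, so siRNAs from it in leaf are not shown. Of 12 PPR genes 0 were called by edgeR and 2 by DESeq2 (camera adjusted p = 0.457, or 0.813 with an estimated correlation). Of 11 genes with a transposable element note 2 were lower (camera adjusted p = 0.427, or 0.602 with an estimated correlation). With the total library size 275 loci were higher and 1135 lower, and with DESeq2 541 and 96. The count of 1047 became 134 without Leaf A replicate 1, 1677 without Leaf B replicate 1, and 583, 291 and 548 without each seedling library in turn.

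Floral tissue was sampled in both labs, and the lab term below was estimated from floral and leaf libraries together. The direct contrast of the floral groups, with 1 mean per group, called 17 mature small RNAs higher and 7 lower in Floral A, and 46 loci higher and 26 lower. Lab A was higher in miR391 (1628 ± 689 RPM in 2 Floral A libraries against 34.2 ± 26.8 in 3 Floral B libraries), miR161.2 (506 ± 246 against 17.9 ± 18.1 RPM), miR169d (207 ± 11.8 against 0.365 ± 0.633 RPM) and miR400 (23.9 ± 3.84 against 0.365 ± 0.633 RPM). At loci, MIR167d gave 6650 ± 3465 against 26.7 ± 22.3 CPM. The floral groups also differed in the first base of reads. Of 24-nt reads, 47.8% started with T in Floral A replicate 4 and 22.2% in replicate 3 (45.0% in its run 1), against 12.2% to 19.7% in Floral B. Most tested mature sequences start with T, and whether this bears on the increases in lab A was not tested. In all, 4 mature small RNAs were higher and 0 lower in lab A by edgeR (16 at an unadjusted p under 0.05), against 1 and 3 with TMM scaling and 3 and 12 with DESeq2. Among loci 44 were higher and 18 lower, against 38 and 52 with the total library size and 110 and 87 with DESeq2.

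By edgeR, miR169d changed by 8.14 ± 2.14 (adjusted p = 0.00873; 338-fold, 95% interval 60.6 to 13339), miR400 by 6.03 ± 1.97 (0.0398; 38.9-fold, 95% interval 6.98 to 1536), miR391 (chromosome 5, 24293160 to 24293180) by 5.56 ± 1.51 (0.00873) and miR161.2 (chromosome 1, 17825722 to 17825742) by 4.817 ± 1.501 (0.0331). With TMM scaling miR400, miR391 and miR161.2 were lost. These were 3 of 27 Brassicaceae-restricted and 1 of 29 developmental miRNAs, the same adjusted over each list alone (camera adjusted p = 0.978 for both, or 0.982 with an estimated correlation). The miR172 family and triggers had 0 called by edgeR and, adjusted over the list alone, 1 and 2 higher, while DESeq2 called 1 lower and 0. Auxin pathway, vegetative phase, nutrient, pollen-associated miRNAs and trans-acting siRNAs had 0 edgeR calls, with 0, 0, 0, 1 lower and 1 higher adjusted over the list alone, and DESeq2 called 1, 0, 2, 0 and 0 lower. Among these lists the smallest camera adjusted p was 0.548, or 0.982 with an estimated correlation. Other values were miR156a 2.73 ± 1.95, miR157a 2.56 ± 1.49, miR159a -4.50 ± 2.26, miR165a 0.82 ± 1.30, miR166a 2.93 ± 1.37, miR168a 2.47 ± 1.43, miR172a 3.43 ± 1.36, miR390a 3.26 ± 1.36, miR845a -5.99 ± 2.25, tasiR-ARF-D7 3.87 ± 1.45 and siR255 0.55 ± 1.84. Those of miR165a and siR255 flipped with TMM scaling and DESeq2. The mature count was 0 without Floral A replicate 4 or Floral B replicate 2, 2 without Floral A replicate 3, Leaf A replicate 2 or Seedling replicate 2 or 3, and 24 without Leaf B replicate 1. The 24-nt share was 44.3% ± 15.6 in Floral A and 59.8% ± 4.32 in Floral B, and the 21-nt share 24.7% ± 9.16 and 9.82% ± 2.77 (both exact permutation p = 0.100, the smallest possible, adjusted p = 0.200). With 1 library left out, the 24-nt difference lay between -26.52 and -4.491 points and the 21-nt difference between 8.393 and 21.35. With distinct sequences these differences were -2.539 and 1.43 points. The pericentromeric share differed by -2.56 points (exact permutation p = 0.300).

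At loci, MIR167d (AT1G31173, chromosome 1, 11137539 to 11137915) changed by 6.59 ± 1.08 (edgeR adjusted p = 0.00326) and alone among the 10 named loci was called in each of the settings that tested it (6 for this locus) and with every library left out. The other increases were AT5G41170 (at least 16.9-fold), AT2G03875 (at least 15.6-fold), AT3G30383 (at least 14.9-fold) and RPF2 (AT1G62670, chromosome 1, 23204256 to 23206822; at least 7.03-fold). The decreases were the long non-coding RNA gene AT2G06535 (-4.28 ± 0.77, adjusted p = 0.00610), AT3G43890 (-4.26 ± 0.81, 0.0121), AT1G54445 (-3.68 ± 0.73, 0.0138) and the overlapping AT1G06837 (-4.26 ± 1.08) and AT1G06833 (-4.19 ± 0.99). AT2G03875 reversed when all matches were divided by their number. Of 12 PPR genes RPF2, AT1G62914 (2.66) and AT5G41170 (7.34) were higher, and 6 adjusted over the list alone (camera adjusted p = 2.06e-07, or 0.352 with an estimated correlation), and 2 with the total library size. The NLR genes and trans-acting siRNA loci had 0 called by edgeR, with 2 and 0 adjusted over the list alone and 2 and 3 by DESeq2, although camera gave adjusted p of 0.00409 and 0.00382, or 0.352 with an estimated correlation for both. The trans-acting loci had TAS1A 2.56 ± 0.97, TAS1B 1.007 ± 0.891, TAS1C 2.42 ± 1.07, TAS2 1.76 ± 0.97, TAS3 1.44 ± 0.95, TAS3b 1.35 ± 0.71, TASIR-ARF 0.98 ± 0.66 and AT3G25795 -2.72 ± 1.10. The miRNA-targeted siRNA sources, genes with siRNA-targeted promoters or repeats and genes with a transposable element note had 0 called by edgeR, with 1, 0 and 2 adjusted over the list alone and 1, 0 and 1 by DESeq2 (smallest camera adjusted p = 0.0914, or 0.459 with an estimated correlation). The count of 62 became 13 without Floral A replicate 3, 6 without Floral A replicate 4, 29 and 35 without Floral B replicates 1 and 2, and 28 without Seedling replicate 2 or 3.

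The silique library asks which small RNAs differ between fruits and flowers, with 1 library against 5. Its spread was taken from the other tissues, so the calls below describe this library and cannot be separated from its own makeup. Listed mature sequences were scarce in it: miR165a had 0 reads against 905 ± 814 RPM in floral tissue, at least 40.7-fold lower, and miR166a stood at 111 against 11403 ± 12896 RPM. Small RNAs were higher in the silique library at ERF11, an ethylene response factor gene (155 reads, 4795 CPM against 11.0 ± 7.15), and AT1G80220 (3495 against 29.96 ± 28.43 CPM). By edgeR 27 loci were higher and 0 lower, with 469 at an unadjusted p under 0.05, and DESeq2 called 33 higher and 51 lower.

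EdgeR called 0 mature small RNAs between silique and floral tissue, with 7 at an unadjusted p under 0.05, and DESeq2 called 1 lower. The median change was -4.67, and every mature list had 0 edgeR calls, also adjusted over the list alone, with camera adjusted p of 0.152 or more (0.982 with an estimated correlation). Values were miR165a -13.08 ± 5.20 (adjusted p = 0.302), miR166a -4.80 ± 2.80, miR172a -4.10 ± 2.66, miR159a -3.97 ± 2.64, siR255 -3.46 ± 2.76, miR157a -3.31 ± 2.64, miR845a -2.95 ± 2.77, miR168a -2.79 ± 2.51, miR156a -2.04 ± 2.59 and miR390a -1.63 ± 2.23. The directions of miR168a and miR390a flipped with TMM scaling and, with miR156a, with DESeq2. Reads of tasiR-ARF-D7 were at least 9.64-fold lower. At loci, edgeR gave ERF11 (AT1G28370, chromosome 1, 9955774 to 9956980) 9.03 ± 1.10 (adjusted p = 3.57e-05) and AT1G80220 7.42 ± 1.07 (0.000470). It also called HEMA1, a tetrapyrrole synthesis gene (AT1G58290; 5 silique reads, 180-fold as a ratio to summed reads, 95% interval 32.4 to 7121), EIF4A-2 (10 silique reads, 120-fold, 95% interval 41.1 to 583) and PLC2 (3 silique reads, at least 36.1-fold). The PLC2 call was lost in 2 alternatives and without any of 7 libraries. These intervals and this floor leave out the counting error of the silique reads, so they are not full bounds. Trans-acting siRNA loci had 0 of 8 called by edgeR and 1 lower by DESeq2 (camera adjusted p = 0.00581, or 0.398 with an estimated correlation). TAS1A was 31.6-fold lower as measured (95% interval 10.8 to 153), TAS3b 13.4-fold lower (95% interval 4.58 to 64.9), and TASIR-ARF 1.77-fold lower (95% interval 0.489 to 14.6). The others were TAS1B -2.94 ± 1.55, TAS1C -1.41 ± 1.68, TAS2 -1.92 ± 1.66, TAS3 -2.98 ± 1.62, and AT3G25795 at 0 reads against 2. The other planned locus lists had 0 called by edgeR, also adjusted over the list alone, and 0 by DESeq2, with camera adjusted p of 0.370 or more. Without Floral B replicate 1 or Seedling replicate 2 the count of 27 loci became 17.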

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

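The explanations of 3 patterns were tested. The 3 tests of AGO4 reads (strand, most frequent sequences, introns) and the test of TMM scaling were chosen after the result was seen, and the tests of messenger RNA fragments and of the silique library were written before. A bootstrap interval of 10000 draws was added to the silique test after its value was seen, and it turned an exclusion into an open question.

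Small RNAs of AGO4, the Argonaute of 24-nt siRNAs, were found in Leaf B replicate 1 alone, with 2897 reads there, 2 in Seedling A replicate 1 and 0 elsewhere. They were looked at because no planned comparison used a locus present in a single library. Fragments of AGO4 messenger RNA could leave few antisense reads: 13.3% were antisense (95% interval 12.1 to 14.5), while 34 other coding loci had a median of 83.2% sense, so this stays open. A few amplified sequences may also account for it, since the 10 most frequent of 197 sequences held 60.6% of the reads. Reads in introns were 0% (95% interval up to 0.132), although introns make up 44.7% of the gene, as spliced AGO4 RNA or an intronless copy would give. However, 2110 of the 2897 reads lay in 1 window of 250 bp (11538000 to 11538249). The reads were thus not spread along the gene, and the interval treats them as independent. Their absence from introns therefore cannot decide whether the RNA was spliced. The AGO4 reads, counted from 20 to 25 nt, were 46.4% 21-nt and 30.4% 22-nt. Among all 18 to 30 nt reads of this library these lengths made up 16.6% and 12.2%. What the lengths mean for the fragment explanation was not tested.

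Small RNA loci lower in floral tissue than in leaf outnumbered the higher ones. Fragments of messenger RNA in the leaf libraries could explain this: the leaf reads of the lower protein-coding loci had a median of 100% on the strand of the gene. Scaling by TMM may also explain it, since with the total library size 21.5% of the calls were lower in floral tissue. Both explanations remain possible, and small RNAs made from these genes in leaf are not shown by these counts.

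The silique library had few miRNA reads. Only 9.23% of its 21-nt reads started with T, against 59.6% ± 18.9 in 5 floral libraries, so a loss of reads that start with T in this library might explain it. Few miRNA reads could by themselves lower that share, since most tested mature sequences start with T. Of its 24-nt reads 3.37% started with T (95% interval 3.24 to 3.50), against 12.2% to 47.8% in the floral libraries. The 12 tested sequences that start with another base had a median change of -3.36 (bootstrap 95% interval -7.52 to -1.23), against -4.88 (-6.40 to -3.47) for 58 that start with T, so a loss of T-starting reads remains open as a partial cause. More structural RNA and organelle reads diluting the library is excluded, as the median was still -4.475 with the library size without those reads.

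The libraries were also regrouped in every other way of the same sizes. For siRNA loci, floral vs leaf, 1 of 56 splits gave as many calls as the real split (1947, against 793 at most otherwise), and floral vs seedling likewise 1 of 56 (1049 against 266). Mature sRNAs, floral vs leaf, had 1 of 56 (19 against 10), and floral vs seedling 1 of 56 (19 against 15). Leaf vs seedling allowed only 10 splits, too few for a share under 0.05: 1 of them for siRNA loci (1047 against 19) and 10 of them for mature sRNAs, where all gave 0. The highest other splits for loci set both Floral A libraries and 1 Floral B library against the rest, which within lab A is the real contrast of tissues. In the floral comparisons the real split thus gave the most calls, 1 split of 56 in each. These splits moved libraries across labs, although lab is part of the model and all seedling libraries came from lab A. Fewer splits exist within a lab, so 1 of 56 overstates what exchange within labs could show.

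Some floral minus leaf changes differed when taken within each lab, in an edgeR model with an interaction of tissue and lab. The lab B side rests on Leaf B replicate 1 alone, so the values below cannot separate the labs from that library. The difference, lab A minus lab B, was 7.53 ± 2.20 for miR156a (adjusted p = 0.0234), 11.22 ± 2.85 for miR156h (0.00687) and -13.48 ± 4.16 for miR398b (0.0304). Among 4826 loci 49 differed, with 904 at an unadjusted p under 0.05. In Leaf B replicate 1, 20.006% of reads held a run of 12 or more A, and in Leaf A replicate 1, 38.0% matched an organelle. Both kinds of reads were part of the library size for size classes and mature sequences. With the library size without them and structural RNA 17 mature small RNAs were called between floral tissue and leaf, 11 higher and 6 lower.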

How the results depend on the processing

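Most named results kept their direction when settings changed, and the cause was not tested where they did not. The balance of higher and lower calls was less stable. With the total library size, called loci went from 744 higher and 1203 lower to 2175 and 595 (floral vs leaf). For leaf vs seedling they went from 777 and 270 to 275 and 1135. Mature sRNAs of floral A vs floral B went from 4 and 0 to 1 and 3 with TMM scaling. Besides the changes of direction of named results with other scalings printed beside the results, none of them called, some differences in shares that did not pass changed sign. The 21-nt share turned in lab A from -3.63 to 3.89 points (floral vs leaf) and from -5.24 to 3.68 (floral vs seedling), and for leaf vs seedling from -1.61 to 3.747 with distinct sequences and to 0.338 without structural RNA or organelle reads. Reversed among named results were miR167d, floral vs leaf, with length variants counted (1.495), miR157a, floral vs leaf, in lab A libraries only (2.331) and AT2G03875, floral A vs floral B, with all matches divided by their number (-1.248). The number of called mature sRNAs became 5 (leaf vs seedling), 15 (floral A vs floral B) and 1 (silique vs floral) with DESeq2. With one mean per group it became 1 (leaf vs seedling) and 24 (floral A vs floral B, then a direct contrast of the floral groups). In lab A libraries only it became 36 (floral vs leaf), 37 (floral vs seedling) and 7 (leaf vs seedling). The number of called siRNA loci became 637 (leaf vs seedling), 197 (floral A vs floral B) and 84 (silique vs floral) with DESeq2, and 668 with no low count filter (leaf vs seedling). With 24-nt reads only it was 673 (floral vs leaf, 444 higher and 229 lower, against 744 and 1203), 310 (leaf vs seedling, 158 and 152, against 777 and 270) and 17 (silique vs floral), while floral A vs floral B had 14 higher and 45 lower. With all matches divided by their number it was 492 (floral A vs floral B). In 1 kb bins it was 3845 (floral vs leaf, 2435 higher and 1410 lower), 3089 (floral vs seedling, 1871 and 1218), 178 (floral A vs floral B, 72 and 106, against 44 and 18) and 45 (silique vs floral). In lab A libraries only it was 2003 (leaf vs seedling, 938 higher and 1065 lower, against 777 and 270). Floral vs leaf in lab A had 1232 higher and 1143 lower, against 744 and 1203. Leaving out each library in turn gave 3 to 20 mature sRNAs for floral vs leaf, 9 to 24 for floral vs seedling, 0 to 1 for leaf vs seedling, 0 to 24 for floral A vs floral B and 0 to 0 for silique vs floral. For siRNA loci it gave 1145 to 2303, 548 to 1339, 134 to 1677, 6 to 89 and 17 to 38 in the same order. With 1 library left out, the 24-nt difference of floral tissue stayed between 35.85 and 43.6 points against leaf and between 28.27 and 37.02 against seedling. With distinct sequences it was 29.01 points against leaf and 11.86 against seedling, and in lab A libraries only 29.36 and 22.64. With a pericentromere of 2 Mb the floral minus leaf share was -3.912 instead of 2.71 points. No paired analysis was possible because the labels name no plant or batch shared between tissues.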

Other observations

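The length of miR167d reads in Floral A differed from that in leaf and seedling. In floral libraries 99.3% of the 3391 reads at the MIR167d locus were 21-nt, against 1.41% of 1989 in leaf and 7.69% of 325 in seedling, while the listed mature sequence has 22 nt. The floral reads came almost wholly from lab A, with 3381 reads against 10 in lab B. The Floral B libraries held the listed 22-nt sequence at 1.10, 10.4 and 9.05 RPM, so a difference between tissues is not shown for lab B. Counting length variants of miR167d turned its floral minus leaf change to 1.495. That setting takes any read with the same first 18 bases. It may include the more abundant miR167a (406 to 10370 RPM in floral tissue, 560 to 3689 in leaf). It therefore cannot by itself show whether a shift in read length underlies the called decrease. The reads at the locus matched the genome only there. In Floral A they were mainly 21-nt, and the count of the listed 22-nt sequence left those reads out. This feature was chosen after its values were seen.

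The NLR disease resistance gene AT5G38850 gave many small RNAs in vegetative tissue: 6603 leaf reads, 86.8% of them 21-nt, and 6601 seedling reads, 81.6% 21-nt, at 20962 ± 16761 CPM in leaf against 100.7 ± 48.6 in floral tissue. In the silique library ERF11 (AT1G28370) gave 155 reads, 4.52% on the strand of the gene and 50.3% 24-nt. In Leaf B replicate 1 AGO1, examined only after AGO4, gave 1729 reads, against 99 and 10 in Leaf A.

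Gene classes in the annotation were tested as lists chosen after the data were seen, and only the pseudogenes in leaf against seedling passed with an estimated correlation. Of 1744 pseudogenes, 8 were higher and 166 lower in leaf than in seedling (camera adjusted p = 2.45e-27, or adjusted p = 0.0268 with an estimated correlation), with 2 and 25 adjusted over the list alone, and 4 and 679 with the total library size. Of 2400 protein-coding genes, 691 were higher and 63 lower, and 789 and 88 adjusted over the list alone (camera adjusted p = 6.03e-25, or adjusted p = 0.352 with an estimated correlation), but 237 and 298 with the total library size, and leaf reads of the higher ones had medians of 100% on the strand of the gene and 14.3% 24-nt. Between floral tissue and leaf 248 pseudogenes were higher and 48 lower, and 131 and 17 adjusted over the list alone (camera adjusted p = 3.85e-07, or 0.352 with an estimated correlation), and between floral tissue and seedling 91 and 189, and 84 and 159 over the list alone (0.0398, or 0.691 with an estimated correlation). Protein-coding genes had 316 higher and 1050 lower in floral tissue than in leaf, and 350 and 1094 over the list alone (2.19e-10, or 0.352 with an estimated correlation) and 281 and 265 against seedling. Long non-coding RNA genes had 76 higher and 43 lower of 262, and 66 and 27 against seedling, and miRNA genes had 31 and 33 of 141, and 34 and 17 against seedling. Between the labs 16 miRNA genes were higher and 1 lower in lab A, and 35 and 8 over the list alone (3.97e-09, or 0.352 with an estimated correlation).

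In Leaf A replicate 2 the gene AT2G07732 gave 48 reads, 1360 CPM, and 0 reads elsewhere. That library lists 0% organelle matches, so reads shared with an organelle were counted as nuclear there.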
